A study of Mus musculus with 6 samples.

How the data were processed

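RNA-seq was measured in 6 libraries of organoids grown from mouse cochlear progenitor cells, 3 from soft gels and 3 from stiff gels. Per the labels' protocols, the organoids were expanded in a medium with growth factors and small molecules and then changed to a differentiation medium with CHIR99021, an inhibitor of the kinase GSK3 that raises Wnt signalling, and LY411575, a gamma-secretase inhibitor that blocks Notch cleavage. They were put into hydrogels of either stiffness at the differentiation stage, so both groups shared the medium. RNA was taken with TRIzol and a column kit, libraries were made with the TruSeq RNA v2 kit, which does not mark the strand, and reads came from an Illumina HiSeq instrument, per the labels' protocols. The labels give the replicate numbers 1 to 3 in each group and do not say whether these were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The stiffness values of the gels and the time spent in them were not given in the sources used here.

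The deposited table held 15016 genes. Its 6 columns of expression per library were taken as FPKM (fragments scaled by gene length and library depth) from the authors, a unit read from the values because the header says only expression. Alignment with TopHat2 2.1.1 to the mouse build mm10 and the use of DESeq2 are recorded per the submitters' processing notes; the read counter and the annotation were not given in the sources used here. The base mean of the deposited table is a signal, the mean of the authors' normalized counts over the 6 libraries, and the log2 fold change with its standard error and the p-value and q-value come from the authors' own comparison of stiff against soft gels, per the file headers. Recomputing the Benjamini-Hochberg adjustment over the listed p-values gave the deposited q-values. Genes missing from the table were not analysed here; it lists 0 mitochondrially encoded genes, so a mitochondrial share of reads was not computed.

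The values for low genes were whole multiples of a step, so reads per gene and library were rebuilt from the FPKM and the base mean. Of all values, 100.0% came out whole within 0.05 reads, and on simulated data with known counts for 15010 genes 100.0% of the counts were rebuilt exactly. The rebuilt depth was 17328469, 17896981 and 17899391 reads in soft replicates 1 to 3 and 17825127, 17179324 and 16108470 reads in stiff replicates 1 to 3, counted over the listed genes. At this depth 3 reads, the limit that a count of 0 allows, correspond to 0.168 to 0.186 CPM (counts scaled to library depth), which covers counting error only. Each library was kept as a separate sample, as labelled.

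The test planned before the data were examined was a count test, with limma on log2 values as the stated alternative for a table without counts. Since the authors deposited FPKM, the alternative became the main test. Genes with a mean FPKM of at least 1 in either group were kept (11780 genes), values were taken as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted with an intensity trend (eBayes with trend) to all 6 libraries without a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are stiff minus soft on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors are SE for log2 fold changes and SD over 3 libraries for FPKM. In data simulated for the stiff-against-soft comparison over 11730 genes, this test recovered 82.7% of genes changed 1.5-fold and 100% of genes changed 2-fold, with 13 false calls among 193. The simulated genes varied independently, with a spread smoothed over genes of similar level, and no library was shifted as a whole. These shares therefore need not hold for the real libraries.

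In all, 35 gene lists (cell type markers, pathways and cell processes) were fixed before the data were examined. The 32 lists with at least 5 tested members went into camera (limma), a competitive test with a preset inter-gene correlation of 0.01, on the same log2 values, with Benjamini-Hochberg adjustment over the lists. In simulated data, the camera test called the 1 list raised 1.5-fold and 0 other lists, but simulated genes varied independently, so this does not cover correlated genes. Gene Ontology terms of 10 to 500 tested genes, as listed in the deposited table, were tested for over-representation among called genes with a hypergeometric test against the 11310 tested genes that carry a term (3007 terms in each direction, Benjamini-Hochberg adjusted). Principal components were computed on the centred log2 values.

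The naming rule, also fixed before, took (A) the 8 largest rises and falls among called genes with a mean of at least 2 CPM, groups that do not overlap and no predicted-gene name, (B) in each list the called member with the lowest adjusted p in each direction, or 2 per direction in a called list, and (C) a set of genes of interest for mechanical signalling and cochlear cell identity. It gave 72 genes. Other genes are named with the remark that they were chosen after their values were seen. Atoh1 and Pou4f3, 2 genes of interest, were not analysed here. Coordinates were taken from the RefSeq annotation of GRCm38, the assembly behind mm10, by Entrez identifier (99.6% of the listed genes matched), for all 72 named genes. Without strand, reads from exons that overlap between genes cannot be told apart. Over whole gene spans, introns included, 25 of the 72 named genes overlap another annotated gene, among them Sox2, Lgr5, Postn, Timp1, Pfkm, Pfkp and Piezo1. Whether their exons overlap was not examined. Gapdh has many processed pseudogenes that can share its reads, so its level is uncertain.

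Alternatives planned before were no filter on low values, a pseudocount of 0.1, a replicate block, an absolute log2 fold change of at least 1, leaving out each library, and for the lists an estimated correlation and a rotation test (fry). The further fits that need deposited counts were not run as first chosen. Median-ratio scaling of the FPKM, limma-voom on the rebuilt reads, a filter of at least 10 FPKM in 3 or more libraries, and the authors' deposited comparison were added in their place after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.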

Results

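Gene expression was compared between cochlear organoids kept in soft gels and in stiff gels, with 3 libraries in each group. The organoids were 3-dimensional cultures of inner ear progenitor cells, and the gels were hydrogels of 2 stiffness levels built on modified gelatin and hyaluronic acid with an adhesion peptide. The comparison asks how the stiffness of the matrix around the cells acts on gene expression during differentiation. Depth ranged from 16108470 to 17899391 reads per library. Ribosomal protein genes, 82 in the table, took 6.80% to 7.80% of the reads, and the 10 most abundant genes took 4.72% to 5.26%.

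Organoids in stiff gels had more RNA of Klf2, Cav1, Sox2 and Lgr5, among others, and less RNA of Ptgs2, Lcn2, Pfkp and Lox, among others. Of these named genes, only Klf2 and Cav1 stayed called whichever library was left out. Of 11780 tested genes, 369 were higher and 316 were lower in stiff gels (limma, Benjamini-Hochberg adjusted p under 0.05), which together is 5.81% of the genes. Most changes were moderate, with a median absolute log2 fold change of 0.54 among the called genes. Changes of at least 1 on the log2 scale were seen in 24 of the higher and 46 of the lower genes. At an unadjusted p under 0.05 there were 2562 of the 11780 genes. Counts of list members at an unadjusted p under 0.05, given below, are to be read against that share. All 685 called genes had groups that did not overlap; among all tested genes 3051 (25.9%) had such groups, where chance gives 10%. In the authors' deposited table, 482 of the same tested genes were higher and 632 lower at q under 0.05, so 43.3% of its calls were higher; 632 genes were called in both in the same direction and 0 in opposite directions. The number of calls depended on single libraries. It was 859 higher and 756 lower without soft replicate 1, 50 and 15 without soft replicate 2, 124 and 85 without soft replicate 3, 65 and 47 without stiff replicate 1, 222 and 216 without stiff replicate 2, and 89 and 54 without stiff replicate 3.

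**Figure D1:**
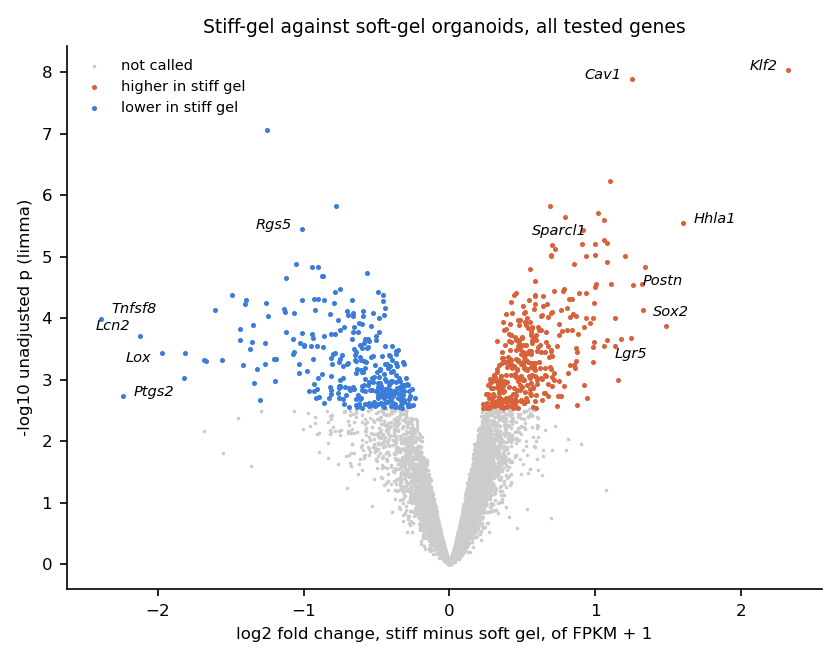
Log2 fold change (stiff minus soft gel, FPKM + 1, horizontal axis) against -log10 of the unadjusted p from limma (vertical axis) for the 11780 tested genes, each a point. The 369 genes called higher are orange and the 316 called lower are blue; Klf2 and Cav1 stand highest.

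Soft replicate 1 stood apart from the other soft libraries. The first principal component held 62.5% of the variance and placed soft replicates 2 and 3 at -16.1 and -18.9, the stiff libraries at 11.7, 7.89 and 17.3, and soft replicate 1 between them at -1.94. On the second component, with 12.3% of the variance, soft replicate 1 stood apart from the other 5 libraries, at 11.9 against -7.43 to 2.21. Soft replicate 1 correlated with soft replicates 2 and 3 at r = 0.992 and 0.991 across genes, and with the stiff libraries at 0.992, 0.992 and 0.990.

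**Figure D2:**
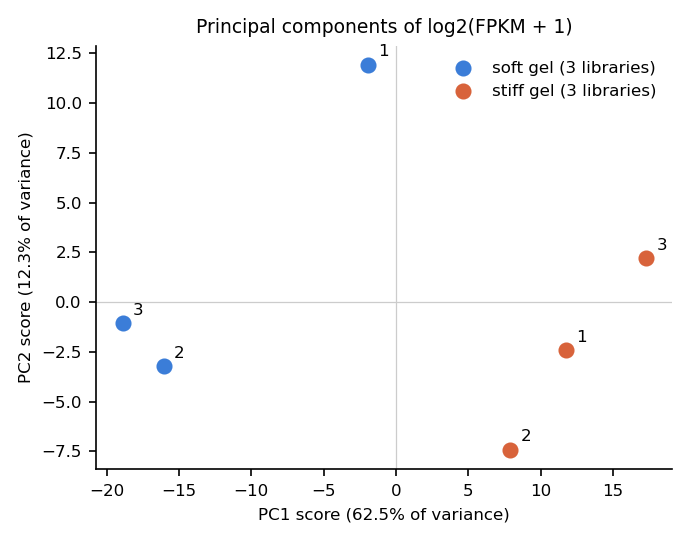
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1), numbered by replicate. Soft replicate 1 lies at -1.94 on the first component, between soft replicates 2 and 3 and the stiff libraries.

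The largest rise was that of Klf2, a zinc finger transcription factor known for its induction by fluid shear in endothelium (chromosome 8, 72319062 to 72321654, build mm10). Its mean went from 1.30 ± 0.0569 FPKM (SD, n = 3) in soft gels to 10.6 ± 1.94 FPKM (SD, n = 3) in stiff gels, a log2 fold change of 2.32 ± 0.12 (SE; limma adjusted p = 7.59e-05); the authors' deposited table gives 3.00. Cav1, the main coat protein of caveolae (chromosome 6, 17306335 to 17341328), rose from 38.1 ± 2.40 to 92.0 ± 2.83 FPKM (log2 fold change 1.25 ± 0.06, limma adjusted p = 7.59e-05). The other large rises were those of Hhla1 (chromosome 15, 65922443 to 65976804; log2 fold change 1.60), the Notch effector Heyl (chromosome 4, 123233556 to 123249870; 1.48), the tight junction gene Cldn23 (chromosome 8, 35824709 to 35826559; 1.34), Sox2 (chromosome 3, 34649995 to 34652461; 1.33), the mitochondrial calcium-binding protein gene Efhd1 (chromosome 1, 87264353 to 87310841; 1.32) and Postn, which encodes the matrix protein periostin (chromosome 3, 54359267 to 54391041; 1.26).

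The largest fall was that of Tnfsf8, which encodes the ligand of CD30 (chromosome 4, 63831202 to 63861508), from 16.3 ± 8.28 to 2.06 ± 0.77 FPKM (log2 fold change -2.39 ± 0.36 SE, limma adjusted p = 0.0109). Ptgs2, the inducible cyclooxygenase gene (chromosome 1, 150100031 to 150108234), fell by 2.24 on the log2 scale, and Lcn2, an iron-chelating acute phase protein gene (chromosome 2, 32384637 to 32387739), fell by 2.12. Lox and Loxl2 encode lysyl oxidases, which cross-link collagen (chromosome 18, 52516060 to 52529867, and chromosome 14, 69608692 to 69695834); they fell by 1.97 and 1.82. Dusp2 (chromosome 2, 127336159 to 127338377), a phosphatase of MAP kinases, and Col23a1 (chromosome 11, 51289679 to 51583925) had log2 fold changes of -1.81 and -1.69. Soft replicate 1 was the lowest soft library for each of these genes, with 4.83 FPKM of Ptgs2 against 24.0 and 23.8 and 14.7 FPKM of Lox against 36.3 and 34.7. Among the 63 genes named by the rule that were called, 12 stayed called whichever library was left out, namely Klf2, Cav1, Hhla1, Cldn23, Efhd1, Postn, Sparcl1, Fosb, Rgs5, Cd14, Ankrd1 and Ddit4. The other 51 lost their call in at least 1 such fit. There were 0 losses without soft replicate 1, 50 without soft replicate 2, 27 without soft replicate 3, 41 without stiff replicate 1, 12 without stiff replicate 2 and 34 without stiff replicate 3, with limma adjusted p up to 0.155.

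**Figure D3:**
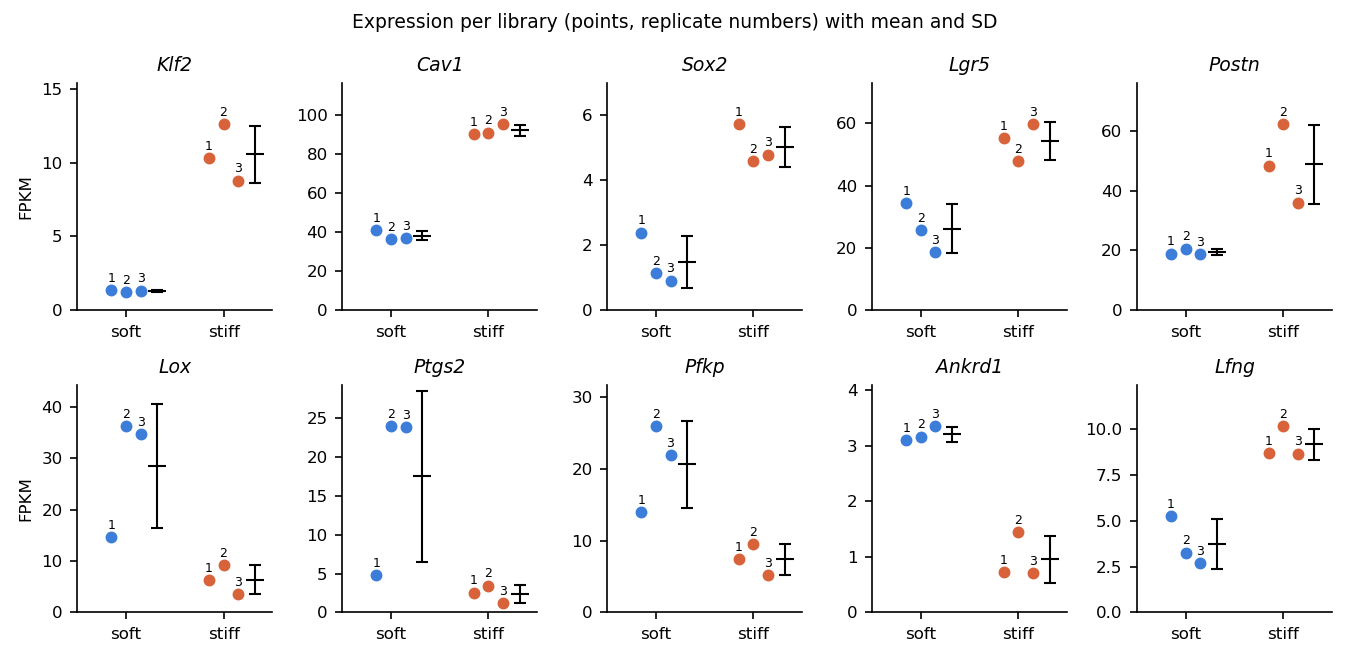
FPKM per library (points, numbered by replicate; vertical axes start at 0) with the mean and SD of 3 libraries (bars) for 10 genes in soft and stiff gels. Klf2 and Cav1 are tightly grouped in soft gels, while soft replicate 1 is low for Lox, Ptgs2 and Pfkp.

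Of the fixed lists, 32 had at least 5 tested members, of which 2 were higher and 14 lower in stiff gels by the list test (camera, limma, preset correlation, adjusted p under 0.05). With an estimated correlation 0 lists were called (adjusted p from 0.366 to 0.472 among the 16 lists), and 3 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves one way on balance, called 0 lists (lowest adjusted p = 0.0582). At an unadjusted p under 0.05 it had 9. Its mixed form, which asks whether members change at all, some up and some down, called 29 of the 32 lists. Lists that camera did not call were among them, such as cartilage genes (fry mixed adjusted p = 1e-04), so the mixed form gives no direction. The direction of each list below is therefore that of the test with a preset correlation. That test also called from 4 to 19 lists in each other split of the 6 libraries into 3 and 3, where the gels are mixed.

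**Figure D4:**
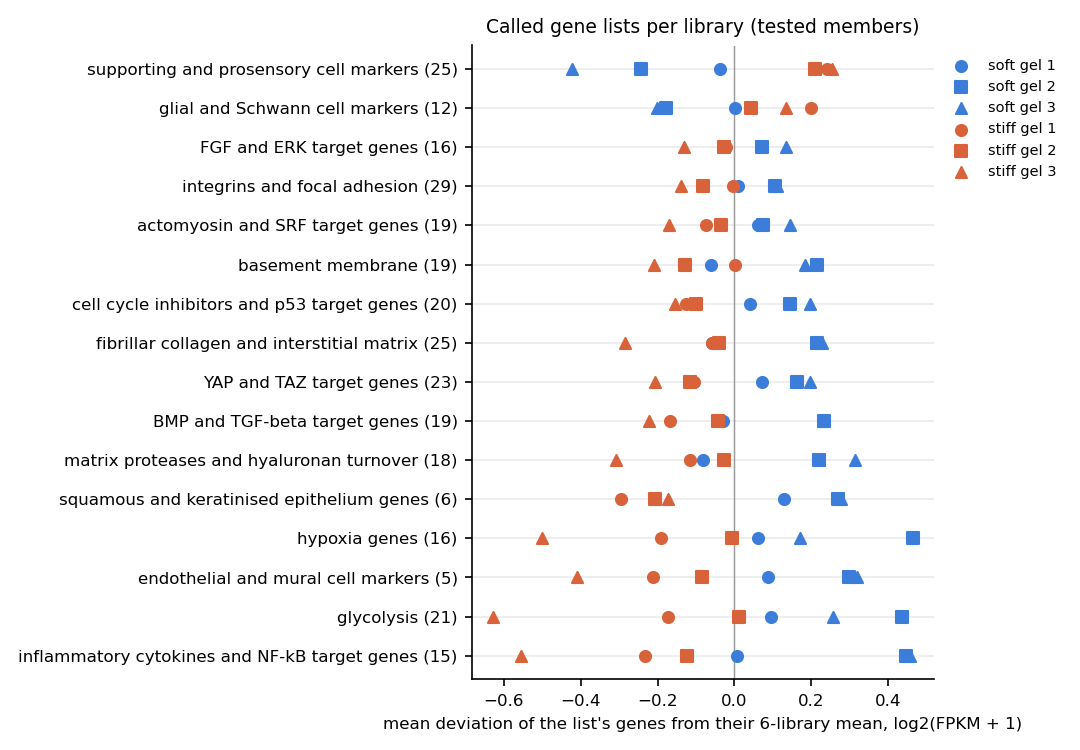
Mean deviation of each called list's genes from their mean over the 6 libraries (horizontal axis, log2(FPKM + 1)) per library, for the 16 called lists with their numbers of tested members. Soft replicates 2 and 3 (blue squares and triangles) lie on the far side of 0 from most stiff libraries, and soft replicate 1 (blue circles) lies between them for most lists.

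Supporting and prosensory cell markers were higher in stiff gels. Of 25 tested members 8 rose and 0 fell; adjusted over the list alone, 17 rose and 1 fell (camera adjusted p = 8.62e-08; adjusted p = 0.366 with an estimated correlation). Sox2, a transcription factor of prosensory and supporting cells, went from 1.48 ± 0.80 to 5.03 ± 0.62 FPKM (SD, n = 3; log2 fold change 1.33 ± 0.19 SE, limma adjusted p = 0.0104). Lgr5, a marker of supporting cells with progenitor capacity and a Wnt target, went from 26.2 ± 7.93 to 54.3 ± 5.97 FPKM (1.06 ± 0.18 SE, limma adjusted p = 0.0159; chromosome 10, 115450314 to 115587780). Sparcl1, a secreted matrix glycoprotein gene, rose from 73.2 ± 10.5 to 146 ± 11.7 FPKM. The other members that rose, named after their values were seen, were Jag1, Otog, Tecta, Emid1 and Gjb6. The list's mean deviation was -0.24 and -0.42 in soft replicates 2 and 3, -0.04 in soft replicate 1 and between 0.21 and 0.25 in the stiff libraries. The epithelial adhesion gene Epcam, in the same list, was at 229 ± 21.1 and 268 ± 16.3 FPKM and was not called (limma adjusted p = 0.147), except without soft replicate 1 (0.0351). Sox2 was not called without soft replicate 2 or stiff replicate 1, and Lgr5 was also lost without stiff replicate 3 (limma adjusted p up to 0.0589 and 0.0785).

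Hair cell markers were not called as a list (camera adjusted p = 0.355), and 22 of the 37 members were in the table, of which 7 were tested. Ush1c, which encodes the stereocilia scaffold harmonin, rose from 24.9 ± 3.57 to 37.9 ± 2.20 FPKM (log2 fold change 0.59), as did Calb2, named after its values were seen, from 5.03 to 10.6 FPKM. Adjusted over the list alone, 2 rose and 1 fell. Myo7a, the hair bundle myosin gene, was at 1.64 ± 0.15 FPKM in soft and 1.64 ± 0.21 FPKM in stiff gels. Glial and Schwann cell markers were higher: 4 of 12 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00559; adjusted p = 0.366 with an estimated correlation). Among them was the myelin gene Pmp22, from 6.92 to 9.56 FPKM. Neuron markers went both ways, with 1 of 8 higher and 2 lower (2 and 2 adjusted over the list alone) and no list call (camera adjusted p = 0.355). Isl1, a transcription factor of sensory precursors and ganglion neurons, rose from 16.6 to 30.7 FPKM, while the growth cone gene Gap43 fell from 5.90 to 1.58 FPKM.

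The Notch list was not called (camera adjusted p = 0.315), with 5 of 18 members higher and 1 lower, or 6 and 2 adjusted over the list alone. Heyl and Lfng, the latter a glycosyltransferase that modifies Notch, rose by log2 fold changes of 1.48 and 1.14, as did Jag1, Hey1 and Nrarp, named after their values were seen. Hes1, a Notch effector also driven by other pathways, fell from 51.9 ± 6.80 to 32.8 ± 4.84 FPKM (log2 fold change -0.65). Both groups had the gamma-secretase inhibitor in the medium. Wnt targets were not called (camera adjusted p = 0.129), with 1 of 22 higher, Lgr5, and 2 lower (2 and 6 adjusted over the list alone). Of the lower members, Myc went from 18.1 to 14.7 FPKM. That list was called lower without soft replicate 3 (camera adjusted p = 0.0306) or without the filter on low values (0.0297). Hes1 and Myc lost their calls without single libraries (limma adjusted p up to 0.0883 and 0.123).

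Mechanosensitive channels were not called as a list. Of 11 tested mechanosensitive channels, 0 were called, over all genes or adjusted over the list alone (limma; 4 had an unadjusted p under 0.05, camera adjusted p = 0.608). Piezo1, a stretch-gated channel gene, was at 7.87 ± 0.47 and 6.45 ± 0.93 FPKM (limma adjusted p = 0.159). Piezo2 was under the filter, with 0.423 ± 0.0297 FPKM in soft and 0.911 ± 0.0725 FPKM in stiff gels. Without the filter Piezo2 was called higher (log2 fold change 0.43, limma adjusted p = 0.016), and in the authors' deposited table it was higher by 1.08 (q = 3.64e-06). In the calcium handling list 1 of 29 members rose, the T-type channel gene Cacna1g, from 4.04 to 6.64 FPKM, and 0 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.326). Among 12 Kruppel-like factors 3 rose and 0 fell, which were Klf2, Klf4 (2.54 to 3.70 FPKM) and, named after its values were seen, Klf6 (4 and 1 adjusted over the list alone; camera adjusted p = 0.224). This list was called higher without soft replicate 3 or without stiff replicate 3 (camera adjusted p = 0.0306 and 0.046). Immediate early genes had 3 of 18 higher and 0 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0698). Fosb rose from 4.36 ± 0.32 to 11.5 ± 2.54 FPKM, and so did Atf3 and, named after its values were seen, Nr4a1. That list was called higher without stiff replicate 3 (camera adjusted p = 1.96e-05), without soft replicate 3 (0.0047), without the filter (0.028), with median-ratio scaling (0.0433) and with limma-voom on rebuilt reads (0.0344).

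YAP and TAZ are transcriptional coactivators whose target genes are widely used as a readout of cell tension, and the target list was lower in stiff gels. Of 23 tested targets 4 fell and 0 rose; adjusted over the list alone, 13 fell and 0 rose (camera adjusted p = 2.28e-07; adjusted p = 0.366 with an estimated correlation). Ankrd1 fell from 3.21 ± 0.13 to 0.962 ± 0.42 FPKM (log2 fold change -1.12 ± 0.14 SE, limma adjusted p = 0.00749) and Amotl2 by a log2 fold change of -0.48; Igfbp3 and Ptpn14, named after their values were seen, also fell. The classical targets Ccn1 and Ccn2 were not called over all genes, at 57.6 ± 8.65 and 41.8 ± 6.64 FPKM (limma adjusted p = 0.0822) and at 27.4 and 20.6 FPKM (0.054). Yap1 was at 46.8 ± 1.34 and 48.4 ± 1.61 FPKM (limma adjusted p = 0.697) and Wwtr1, the TAZ gene, at 33.6 ± 2.90 and 28.6 ± 0.97 FPKM (0.113). Without soft replicate 1, Ccn1, Ccn2 and Wwtr1 were called lower (limma adjusted p = 0.0148, 0.0235 and 0.0369), and Ccn2 also without stiff replicate 2 (0.0281). The authors' deposited table has Ccn1 and Ccn2 lower (q = 0.0039 and 0.00404).

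Adhesion and contractile genes were lower. Among 29 integrin and focal adhesion genes 6 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 1.04e-05; adjusted p = 0.366 with an estimated correlation). Integrin alpha 3 (Itga3) went from 49.2 to 32.7 FPKM and the tensin gene Tns3 from 22.3 to 14.4 FPKM, against the rise of Cav1. Actomyosin and SRF targets had 3 of 19 lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 3.29e-05; adjusted p = 0.366 with an estimated correlation). The called members had small changes, such as Cald1 (log2 fold change -0.32) and Tpm1 (-0.31), and these calls were lost when any library other than soft replicate 1 was left out (limma adjusted p up to 0.148 and 0.155).

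Among the matrix lists single members went both ways. In the fibrillar collagen and interstitial matrix list 5 of 25 members fell and 3 rose (11 and 6 adjusted over the list alone; camera adjusted p = 0.0132; adjusted p = 0.472 with an estimated correlation). Lox and Loxl2 fell most, Col5a3 went from 3.32 to 1.25 FPKM and Col12a1 from 5.17 to 3.21 FPKM, whereas Postn rose from 19.4 ± 1.01 to 48.8 ± 13.2 FPKM and the elastin gene Eln from 4.78 to 7.06 FPKM. Basement membrane genes had 3 of 19 lower and 0 higher (8 and 2 adjusted over the list alone; camera adjusted p = 4.98e-05; adjusted p = 0.425 with an estimated correlation), among them Col4a2 (45.9 to 32.7 FPKM) and Nid2 (13.8 to 7.78 FPKM). Proteases and hyaluronan enzymes had 3 of 18 lower and 0 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.425 with an estimated correlation). Timp1, an inhibitor of metalloproteases and so opposite in action to them, fell from 68.2 to 28.2 FPKM, and the hyaluronan synthase gene Has2 from 1.17 to 0.443 FPKM. BMP and TGF-beta targets had 4 of 19 lower and 0 higher (9 and 1 adjusted over the list alone; camera adjusted p = 1.04e-05; adjusted p = 0.366 with an estimated correlation), with Msx2 going from 6.47 to 3.73 FPKM and Atoh8 from 13.2 to 7.40 FPKM. Soft replicate 1 lay below soft replicates 2 and 3 in these lists, with a mean deviation of -0.06 for fibrillar and -0.06 for basement membrane genes, -0.08 for the proteases and -0.03 for the BMP and TGF-beta targets. It was within the range of the stiff libraries for the first 3 of these lists, whose highest stiff values were -0.04, 0.00152 and -0.03, so the groups overlapped there; for the BMP and TGF-beta targets the highest stiff value was -0.04. The fibrillar list was not called without stiff replicate 3 (camera adjusted p = 0.0825), nor were the proteases without the filter on low values (0.0513). Cartilage genes were not called (camera adjusted p = 0.504), with 2 of 9 lower and 0 higher (3 and 2 adjusted over the list alone); of these Cnmd, which encodes chondromodulin, went from 81.3 to 49.0 FPKM.

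Glycolysis genes were lower in stiff gels, with a median log2 fold change of -0.50 over 21 genes (camera adjusted p = 5.01e-08; adjusted p = 0.366 with an estimated correlation). Only 2 members fell and 1 rose over all genes tested, whereas 15 fell and 1 rose adjusted over the list alone. The platelet-type phosphofructokinase gene Pfkp fell from 20.6 ± 6.07 to 7.39 ± 2.17 FPKM (log2 fold change -1.36 ± 0.23 SE, limma adjusted p = 0.0152) and Gapdh from 92.0 ± 6.44 to 64.6 ± 6.25 FPKM, while the muscle-type phosphofructokinase gene Pfkm rose from 22.9 to 28.4 FPKM. Hypoxia genes had a median of -0.48 over 16 genes, with 2 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 4.55e-06; adjusted p = 0.366 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, went from 92.7 to 65.6 FPKM and the oxygen sensor gene Egln3 from 3.53 to 2.00 FPKM, and Mxi1, an antagonist of Myc, rose from 9.93 to 14.2 FPKM. Libraries within a group differed widely for both lists. The mean deviation of glycolysis genes was 0.09, 0.44 and 0.26 in soft replicates 1 to 3 and -0.17, 0.01 and -0.63 in stiff replicates 1 to 3. Oxidative phosphorylation genes were not called, with 0 of 33 past the limma threshold (over all genes and adjusted over the list alone; 2 at an unadjusted p under 0.05; camera adjusted p = 0.268), although that list was called higher without stiff replicate 1 (0.00309). Cholesterol synthesis genes had 1 of 22 lower, Sqle at 66.7 and 53.6 FPKM, and 0 higher (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.348). The unfolded protein and integrated stress response had 1 of 22 higher, Atf3, and 0 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.355).

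Inflammatory cytokines and NF-kB targets were lower, with a median log2 fold change of -0.50, or -0.25 without the filter on low values. Of 15 members 5 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 1.04e-05; adjusted p = 0.366 with an estimated correlation). Lcn2 fell from 56.6 ± 24.6 to 12.3 ± 5.25 FPKM and the chemokine gene Ccl7 from 3.61 ± 0.90 to 1.21 ± 0.54 FPKM, next to Ptgs2 and, named after their values were seen, Ccl2 and Ccl20. Tnfaip2 rose from 11.4 to 21.5 FPKM. The list's mean deviation was 0.45 and 0.46 in soft replicates 2 and 3, 0.01 in soft replicate 1 and -0.23, -0.12 and -0.56 in the stiff libraries. Ptgs2 was called in 1 of the 6 fits that leave out a library. The interferon response had 0 of 10 members called, over all genes or adjusted over the list alone (limma; 4 at an unadjusted p under 0.05), and no list call (camera adjusted p = 0.697).

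Fibroblast and otic mesenchyme markers were not called (camera adjusted p = 0.571), with Postn as the 1 of 16 that rose and 0 lower (2 and 1 adjusted over the list alone). Endothelial and mural cell markers were lower, with 2 of 5 lower and 0 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.00278; adjusted p = 0.366 with an estimated correlation). Rgs5, a regulator of G protein signalling known from pericytes, went from 18.2 ± 2.18 to 8.50 ± 0.84 FPKM and Kdr, the VEGF receptor gene, from 24.7 ± 5.17 to 10.7 ± 2.04 FPKM. Squamous and keratinised epithelium genes were lower, with 2 of 6 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.366 with an estimated correlation), Sprr1a from 10.2 to 3.68 FPKM and Krt17 from 2.01 to 0.82 FPKM. Of the macrophage and immune cell markers 2 were tested, too few for the list test, and Cd14, a coreceptor for bacterial lipopolysaccharide, fell from 2.24 ± 0.37 to 0.872 ± 0.0573 FPKM (also 1 lower adjusted over the list alone). Melanocyte and stria vascularis markers had 0 of 5 called by limma (1 higher and 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05; camera adjusted p = 0.997). Motile cilia genes had 3 tested members with 0 called by limma, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and erythroid markers had 0 tested members.

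Proliferation genes did not differ between the gels at the limma threshold, with 0 of 32 called over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05; camera adjusted p = 0.263). Mki67 was at 47.3 ± 5.26 FPKM in soft and 43.8 ± 5.50 FPKM in stiff gels (SD, n = 3; limma adjusted p = 0.621). Without soft replicate 2 this list was called lower (camera adjusted p = 0.011). Cell cycle inhibitors and p53 targets were lower in stiff gels, with 6 of 20 lower and 0 higher (11 and 2 adjusted over the list alone; camera adjusted p = 1.11e-05; adjusted p = 0.366 with an estimated correlation). Cdkn1c, which encodes the inhibitor p57, fell from 89.4 ± 12.1 to 47.0 ± 7.98 FPKM and the p53 target Phlda3 from 25.9 ± 1.25 to 18.8 ± 0.73 FPKM. FGF and ERK targets were called lower as a list (camera adjusted p = 0.00939; adjusted p = 0.424 with an estimated correlation), although the 1 called member of 16, the FGF antagonist gene Il17rd, rose from 20.8 to 30.3 FPKM (1 higher and 2 lower adjusted over the list alone). Soft replicate 1, with a mean deviation of -0.026, was within the range of the stiff libraries (-0.131 to -0.023), so the groups overlapped. Without stiff replicate 3 that list was not called (camera adjusted p = 0.055).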

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

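The counts of genes were refitted under settings fixed before the data were examined; median-ratio scaling, limma-voom on rebuilt reads, the higher expression threshold and the authors' deposited comparison were added afterwards. Against 369 higher and 316 lower genes, a required absolute log2 fold change of at least 1 left 24 higher and 46 lower, and FPKM of at least 10 in 3 or more libraries left 188 and 153. Median-ratio scaling gave 315 higher and 326 lower, limma-voom 403 and 468, and the authors' deposited comparison 482 and 632 among the tested genes, so in these settings more genes were lower than higher. Leaving out 1 library gave from 50 to 859 higher genes and from 15 to 756 lower genes, with the lowest counts without soft replicate 2 and the highest without soft replicate 1. Without the filter on low values 288 genes were higher and 221 lower. Of the 685 called genes, 444 were kept without the filter, 560 with replicate numbers as blocks and 672 with a pseudocount of 0.1. Median-ratio scaling kept 625, limma-voom 632 and the authors' comparison 632. Of the 359 that passed the FPKM threshold of 10, 341 were kept. Leaving out 1 library kept from 65 (without soft replicate 2) to 674 (without soft replicate 1). Called in each of these 6 fits were 53 genes, 40 higher and 13 lower.

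Against 2 higher and 14 lower lists (camera), an estimated correlation gave 0 and 0, and the rotation test fry gave 0 and 0, with 3 and 9 lists at an unadjusted p under 0.05. Leaving out 1 library gave from 2 to 4 higher lists and from 12 to 15 lower lists, with 4 higher without soft replicate 3 and without stiff replicate 3.

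Replicate numbers taken as blocks gave 381 higher and 329 lower genes. The deviations of libraries sharing a number correlated at 0.009, 0.219 and -0.211. These values rest on 3 libraries per group and were not set against libraries of unlike number. They therefore do not settle whether the numbers pair the libraries.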

Other observations

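The gene groups in this paragraph and the next were chosen after their values were seen. Of 7 genes of the inner ear's acellular membranes 5 were called higher in stiff gels and 0 lower (limma): Otoa from 8.12 to 18.6 FPKM, Oc90 from 60.5 to 128 FPKM, Tecta, Otog and Otol1, but not Tectb (adjusted p = 0.259) or Otogl (0.0712). Tecta, Tectb, Otog and Otogl also belong to the supporting and prosensory list above, so this group is not separate from that list. Otoa and Oc90 stayed called whichever library was left out, while Tecta, Otog and Otol1 lost their call in 3, 3 and 4 of these 6 fits (adjusted p up to 0.0714, 0.0809 and 0.106). Of 7 caveolar genes 3 rose, Cav1, Cavin3 (22.1 to 36.6 FPKM) and Cavin2, Cavin1 was called lower (log2 fold change -0.29), and Cav2, Cavin4 and Ehd2 were not called. The calls of Cavin1 and Cavin2 were lost in 6 and 5 of the fits (adjusted p up to 0.137 and 0.153).

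Lysyl oxidase genes had 3 of 5 lower and 0 higher, with Loxl4 going from 6.03 to 1.95 FPKM beside Lox and Loxl2, and the 3 metallothionein genes Mt1, Mt2 and Mt3 fell. Claudins and occludin had 5 of 11 higher and 1 lower. Called whichever library was left out were 1 of the 3 lysyl oxidases (Loxl4), 1 of the 3 metallothioneins (Mt2) and 2 of the 6 claudin and occludin calls (Cldn6 and Cldn23); adjusted p of the others reached 0.109, 0.144 and 0.135 in these groups. Among Gene Ontology terms, 99 were over-represented in the lower genes and 1 in the higher genes (hypergeometric test, Benjamini-Hochberg). The hypergeometric test treats genes as independent, so its p-values are too small where genes of a term vary together. It was run only on the calls of the main fit, and without soft replicate 2 the number of lower genes was 15. Collagen-containing extracellular matrix held 27 lower genes of 187 where 4.99 would come by chance (adjusted p = 1.88e-09), and inflammatory response held 21 of 150 (adjusted p = 6.85e-07). Matrix genes went both ways, however. The term extracellular matrix held 16 lower genes of 149 (hypergeometric adjusted p = 0.000448) and 15 higher genes (0.0939). The term for the higher genes was anchored component of membrane, with 10 of 55 (adjusted p = 0.022).

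The tests on other splits, endothelial cells, fibroblasts and the reads of soft replicate 1 were chosen only after the result was seen, and median-ratio scaling was an added setting. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split had 685 called genes against at most 0 in another split, and 1 of the 10 splits reached the real value. For lists the real split had 16 called and the highest other 19, in the split of soft replicate 1 with stiff replicates 1 and 3, and 3 of the 10 splits had at least as many. Each of the other splits called at least 4 lists, although it called 0 genes. A list call by camera with the preset correlation therefore need not reflect the gels.

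Klf2 rose by 2.32 on the log2 scale. More endothelial cells in the stiff-gel libraries are argued against by the highest fold change of a tested endothelial or mural marker, 0.112 ± 0.09 (SE) for Tek, where 1.16 was the bound. This covers only the 5 markers past the filter on low values, of 16 listed and 12 in the table. The markers under the filter were not examined, so a rise of rare endothelial cells seen only in those is not covered. Scaling between libraries is argued against by how little another scaling moved the genes. The median log2 fold change of all tested genes was 0.0266, and 7e-04 with median-ratio scaling of the FPKM. Size factors of the rebuilt reads, which also carry depth, ran from 0.9519 to 1.0302. With median-ratio scaling the log2 fold change of Klf2 was 2.298 ± 0.119 (SE), an outcome that so small a shift all but fixed. A handling response seen in all immediate early genes stays open: the median log2 fold change of Fos, Egr1, Ier2 and Jun was 0.271 (interquartile range 0.196) with 4 of 4 above 0, between the bounds set beforehand, under 0 if not the cause and at least 1 if the cause, and Fosb, Nr4a1 and Atf3 rose. Gel stiffness, which the design names, stays open as untested.

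Glycolysis, hypoxia, inflammatory and YAP target genes were lower in stiff gels (camera; adjusted p = 0.366 for each with an estimated correlation). Fewer fibroblasts are argued against for glycolysis and hypoxia genes by a median log2 fold change of 0.048 over the fibroblast and mesenchyme markers (interquartile range 0.318), against list medians of -0.50 and -0.48. This holds for the markers as a set only, since 9 of 16 were above 0 and 7 below. Col3a1 had a log2 fold change of -1.002, not called over all genes, and Postn one of 1.256. Fewer fibroblasts stay open for YAP target genes, whose gap of 0.31 is within that interquartile range, and for inflammatory genes, whose gap without the filter on low values, 0.259, is within the spread of 0.269 found there. For fewer immune cells, the 7 leukocyte markers summed to 11.48 ± 2.46 CPM in soft and 9.81 ± 2.05 CPM in stiff gels. The called lower genes of these lists lost 337.3 CPM, and all tested glycolysis genes lost 4034.2 CPM. The rule set beforehand took a sum in soft gels below the 337.3 CPM as arguing against fewer immune cells, and this was met. That rule assumes how strongly leukocytes express the markers, and no value here ties a share of leukocytes to the loss. A second condition, absent from that rule, asked that the markers' change lie above the list medians beyond its error. It was not met, with a log2 change of -0.225 ± 0.242 (SE), so fewer immune cells were left open. Oxygen supply, cell density and gel stiffness were not separated by this design and stay open as untested.

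Soft replicate 1 lay between the groups on the first component and apart from all other libraries on the second. Fewer reads are argued against by a difference of -3.18% from the other soft libraries, under the bound of 10%. Stiff-gel material mixed into this library is argued against by Klf2, which stood at 0.0062 of the way to the stiff level (95% interval -0.0404 to 0.0528), where glycolysis genes stood at 0.359. No biological explanation was tested.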
